A study of Mus musculus with 7 samples.

How the data were processed

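The data are gene-level read counts from 7 RNA sequencing libraries of primary mouse OPCs, 4 untreated controls and 3 treated with 20 µM phenylephrine for 1 hour. The deposited table holds whole-number counts per Ensembl gene with no normalization, 1 column per library. Per the submitters' processing notes, bcl2fastq 2.17, STAR and HTSeq were used with the mouse builds GRCm38 and mm10. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. Per the labels' protocols, libraries were made with a SMART-Seq v4 low-input kit and Nextera XT, which amplify full-length cDNA and do not mark strand, so reads of antisense or overlapping genes cannot be told apart, and amplification makes reads non-independent molecules. The labels' treatment and extraction protocols also describe tamoxifen, virus injection and immunoprecipitation in mouse cortex, which do not match libraries labelled as wild-type primary cells, and it stays open whether any of these steps applied here. The labels name no vehicle for the controls.

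Groups and replicate numbers were taken from the sample titles. The table listed 48795 gene identifiers, of which 48349 had a symbol, and no row without a gene and no unmapped column of values (0). Library totals were 14446633, 13062120, 15634804 and 17962339 counts for controls 1 to 4 and 14094801, 12837463 and 17425694 for PE replicates 2 to 4, at which 3 counts correspond to 0.167 to 0.234 CPM. Intervals and floors of this kind cover counting error only. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom between 12.0 and 102.8, where 1 is sampling noise), so all were counted as separate samples. Nothing states that replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be partly technical.

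From the counts, edgeR 4.0.16 in R 4.3.3 was used with TMM normalization, the default filterByExpr filter (minimum count 10, minimum total 15), which left 15934 genes, and the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The planned design had the treatment group alone. A second fit, also fixed beforehand, added the replicate number as a block. Whether the numbers pair the samples was decided from the correlation of deviations from the group means before the calls were compared. It was 0.74, 0.67 and 0.79 for numbers 2, 3 and 4, each above the limit of 0.1, and each of the 3 PE libraries correlated best with the control of its own number. The limit alone does not single out the pairs. PE replicate 2 had 0.67 with control replicate 1, PE replicate 4 had 0.36 with control replicate 3 and PE replicate 3 had 0.22 with control replicate 4. The library codes in the titles also share a number within each pair. The numbers were therefore taken to pair the samples, and the blocked values are reported beside the unblocked ones. In the blocked fit control replicate 1 has no partner and carries no weight in the treatment effect. CPM values are counts scaled to the TMM-adjusted library size, and log2 CPM used a prior count of 2. Standard errors were derived from the fold change and the F statistic. Its spread estimate draws on all genes, so these errors can be smaller than the spread of a gene between pairs.

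32 gene lists were fixed before the data were examined, covering signalling responses, receptors, lineage, proliferation, metabolism, stress, other cell types and RNA quality. The 31 with at least 5 measured members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with the estimated correlation and fry as alternatives. fry tests whether members move on balance in one direction and does not compare a list with other genes. Several lists share members, so their results are not independent. The rule for named genes was also fixed beforehand. It took the 12 genes per direction with the largest change among those past the threshold without overlap of the libraries, filled up by smallest unadjusted p where fewer passed (predicted genes with Gm or Rik names left out), up to 4 members of each list, and 23 genes chosen for the treatment and cell type. Since no gene passed without the pairs, the same rule of largest change was applied to the paired fit after the data had been seen, taking genes that moved the same way in all pairs. Sik1, Pde4b, Pde4d, Vgf, Scg2, Rora, Btg2, Maff, Kif20b, Aurka, Dusp6, Spry2, Spry4, Etv5, Ier5, Vcl, Ccn1 and Col1a1 are named outside the rule as the members behind a count and were chosen after their values were seen. Some genes that the rule or a count would name are not reported here. Gene positions and overlaps came from GENCODE M21 on GRCm38, which covered 15894 of the tested genes.

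The procedure was tested on simulated counts with the means and library sizes of the real libraries and 50 genes changed at each of 4 fold sizes among 15934. Means and spread came from the paired fit, so part of the gain from the block was built in. Each fold was the same in every pair, and changed genes were drawn from those with an average log2 CPM above 1. The recovery below does not cover genes with lower counts or changes that vary between pairs. Without the block the test recovered 2%, 20%, 64% and 66% of genes changed 1.5-, 2-, 3- and 4-fold with 0 false calls. With the block it recovered 92%, 92%, 100% and 100%, and 23 of its 233 calls (9.87%) were false, above the nominal rate. The other 18 calls were members of a simulated list of 20 further genes raised 1.5-fold. Alternatives were other normalizations (DESeq2 size factors, upper quartile), no filter or a stricter filter (CPM of at least 1 in 3 libraries), robust estimation, a threshold of 0.1, a minimum fold of 1.5, DESeq2 1.42.0, limma-voom with and without sample weights, each replicate left out in turn and, added after the data were seen, the same set of choices in the paired fit and limma-voom with the number as a random block. Figures were drawn with matplotlib 3.10.9.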

Results

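Gene expression was measured by RNA sequencing in primary mouse oligodendrocyte precursor cells (OPCs), the proliferating glial cells that give rise to myelinating oligodendrocytes. The cells came from wild-type CD-1 pups of postnatal days 4 to 7, of both sexes in equal numbers. They were either left untreated or given phenylephrine (PE), an agonist of α1-adrenergic receptors, at 20 µM for 1 hour. There were 4 control libraries, numbered 1 to 4, and 3 PE libraries, numbered 2 to 4, so that 3 numbers had both a control and a treated library and control replicate 1 had no treated partner. The libraries held between 12837463 and 17962339 counted reads, 22202 to 23154 genes with at least 1 read, and 2.05% to 2.53% of counts in mitochondrially encoded genes. The series asks how noradrenergic signalling acts on OPCs and their proliferation, and this comparison asks which transcripts differ after 1 hour of α1-adrenergic stimulation.

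The libraries separated by replicate number rather than by treatment. The first principal component carried 65.1% of the variance and placed numbers 1 and 2 on one side and numbers 3 and 4 on the other, while each PE library lay closest to the control library of its own number. The values below are therefore given mainly as changes within the 3 pairs.

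**Figure D1:**
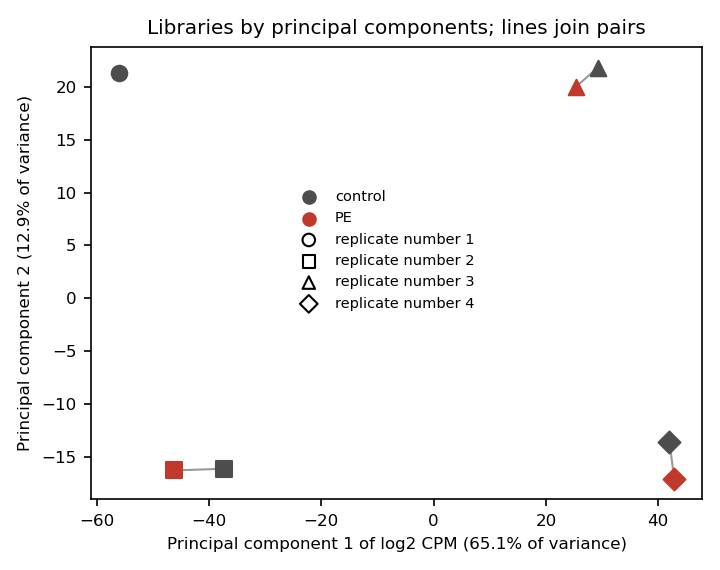
Principal components 1 and 2 (65.1% and 12.9% of the variance) of log2 CPM (library-scaled counts) of the tested genes, with 1 point per library, grey for control and red for PE, a symbol for each replicate number and a line joining the libraries of a pair. Libraries of the same number lie together, and numbers 1 and 2 lie apart from 3 and 4 along the first component.

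After 1 hour of PE, 86 of 15934 tested genes differed within pairs, 80 of them higher and 6 lower (edgeR quasi-likelihood test with the replicate number as a block, Benjamini-Hochberg adjusted p under 0.05). When the pairs were ignored, the same test called 0 genes. Among the strongest changes were the nuclear receptors of the NR4A family, which are classic rapid-response transcription factors. Within pairs Nr4a3 rose 3.52-fold (log2 change 1.82 ± 0.23 SE, 3 of 3 pairs, adjusted p = 0.000784), Nr4a2 rose 3.13-fold (1.65 ± 0.19, adjusted p = 0.000502) and Nr4a1 rose 2.48-fold (1.31 ± 0.17, adjusted p = 0.000865). The size of the rise varied widely between pairs 2, 3 and 4. The log2 ratios were 0.985, 1.83 and 3.20 for Nr4a3, 0.955, 1.86 and 2.60 for Nr4a2 and 0.552, 1.47 and 2.02 for Nr4a1. The SE given here and below comes from the fit and is not the spread between pairs. The genes with the smallest adjusted p were Cd14, the co-receptor for bacterial lipopolysaccharide, and Fgfr2, a fibroblast growth factor receptor. Cd14 went from 4.07 ± 0.887 CPM (SD, n = 4) in control to 12.3 ± 3.79 CPM (n = 3) in PE, 2.82-fold within pairs. Fgfr2 went from 35.2 ± 6.54 to 65.2 ± 2.40 CPM, 1.73-fold within pairs, and for both genes all PE libraries lay above all control libraries. "Rose" and "fell" are used below only for genes past this paired test.

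With predicted genes left out, the other genes among the 12 with the largest increases were Tac1, which encodes the substance P precursor (log2 change 1.97 ± 0.36), Cytip (1.95 ± 0.37), Ccrl2 (1.84 ± 0.30), the small GTPase gene Gem (1.46 ± 0.16), the natriuretic peptide clearance receptor Npr3 (1.36 ± 0.21), prostaglandin synthase Ptgs2 (1.25 ± 0.19), the secreted stanniocalcin Stc1 (1.17 ± 0.14) and the AP-1 subunit Fosl2 (1.03 ± 0.16). Tac1, Cytip and Ccrl2 averaged below 1 CPM in control, so their folds rest on few reads. Ptgs2 averaged 10.2 CPM in control and 10.6 CPM in PE, so its rise was seen within pairs and not between the group means. The 6 genes that fell did so by less. The urokinase gene Plau fell by 0.98 ± 0.16 on the log2 scale, the oligodendrocyte-lineage factor Sox8 by 0.37 ± 0.07, the kinase Map3k1 by 0.37 ± 0.06, the cyclin F gene Ccnf by 0.33 ± 0.05, Inka2 by 0.30 ± 0.04 and the lineage factor Olig2 by 0.19 ± 0.04 (fold 0.875, adjusted p = 0.0334). Each of the 86 genes moved the same way in all 3 pairs, the median size of the change was 0.44 on the log2 scale, and 13 genes rose more than 2-fold. For 16 of the 86 the control and PE libraries did not overlap, a separation that 1.26% of all tested genes showed. Where libraries are exchangeable, chance gives it to 5.71% of genes. The 86 were selected by their PE change in these same libraries, so the 16 are not separate support.

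In the mouse assembly GRCm38 with the GENCODE M21 annotation, Cd14 (ENSMUSG00000051439) lies on chromosome 18 from 36725067 to 36726798, Nr4a1 (ENSMUSG00000023034) on chromosome 15 from 101254269 to 101274795, Nr4a2 (ENSMUSG00000026826) on chromosome 2 from 57106830 to 57124003, Nr4a3 (ENSMUSG00000028341) on chromosome 4 from 48045153 to 48086447 and Olig2 (ENSMUSG00000039830) on chromosome 16 from 91225457 to 91228677. No other tested gene overlaps these 5. Fgfr2 (ENSMUSG00000030849) is annotated there on chromosome 7 from 130162451 to 133123350, a span that overlaps many other genes, and Dusp1, Junb, Sox8, Spry1, Gpr17 and Ccnd1 each overlap another tested gene. The library kit does not mark strand, so their values are less certain.

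**Figure D2:**
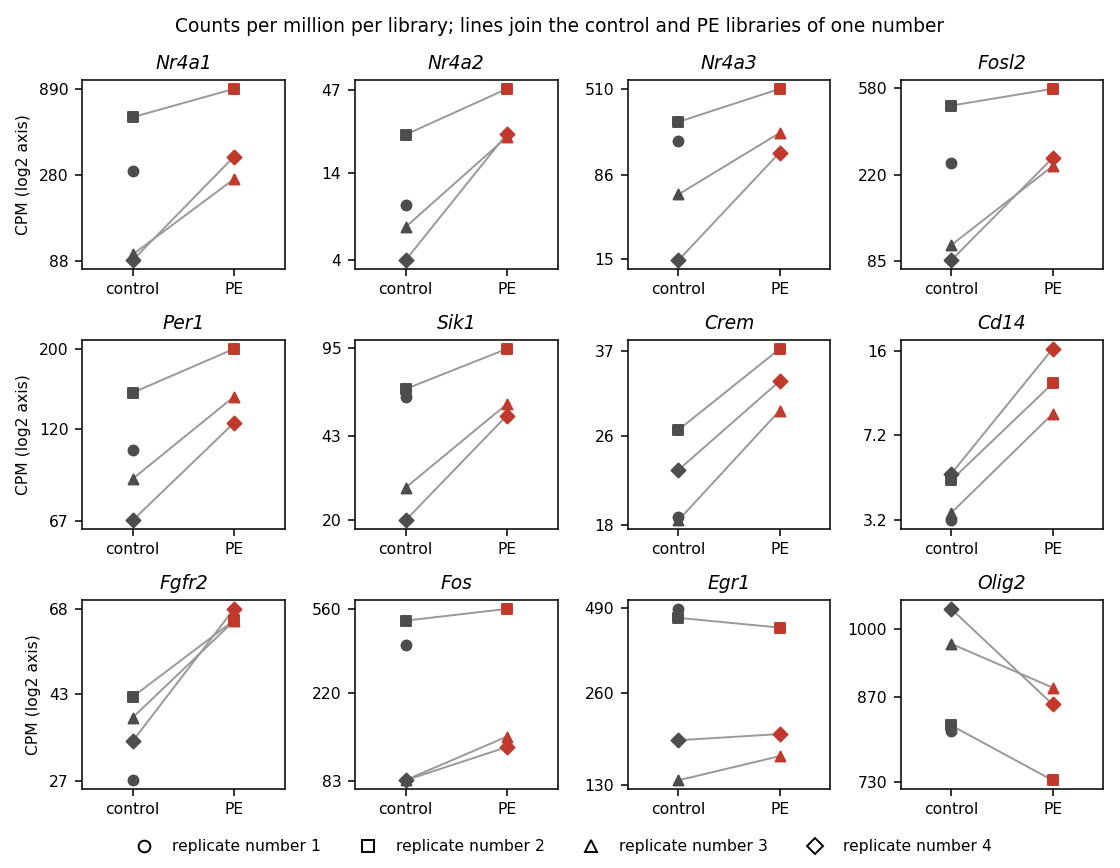
CPM on a log2 axis, with a separate range for each gene, in the 4 control and 3 PE libraries for 12 genes. Grey points are control, red points are PE, symbols give the replicate number and lines join the libraries of a pair. Nr4a1, Nr4a2, Nr4a3, Fosl2, Per1, Sik1, Crem, Cd14, Fgfr2 and Fos were higher after PE in each of the 3 pairs and Olig2 was lower, although control replicate 2 often lay above the PE libraries of pairs 3 and 4, while Egr1 did not pass the test (log2 change 0.07 ± 0.06).

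The cAMP and CREB target genes formed the group with the largest change. Of 19 measured members 13 rose, 0 fell and 6 did not pass (15 rose when adjusted over the list alone), with a median log2 change of 0.67. The members that rose were Nr4a1, Nr4a2, Nr4a3, Gem, the salt-inducible kinase Sik1 (0.95 ± 0.11), the secretory granule genes Scg2 (0.83 ± 0.11) and Vgf (0.73 ± 0.12), the phosphatase Dusp1 (0.71 ± 0.10), the clock gene Per1 (0.67 ± 0.07), Crem (0.55 ± 0.08), Fos (0.45 ± 0.07) and the cAMP phosphodiesterases Pde4d (0.43 ± 0.06) and Pde4b (0.25 ± 0.05). Bdnf had a log2 change of 0.85 ± 0.26 and did not pass (adjusted p = 0.370). The list mean was higher after PE by 0.42, 0.74 and 0.97 in pairs 2, 3 and 4. The list ranked above other genes in the paired camera test with the preset correlation (adjusted p = 5.05e-83), and this call was lost with adjusted p = 0.243 with an estimated correlation. By fry within pairs the list was not called (adjusted p = 0.226). The number of called members differed between methods, at 13 with limma-voom and the block, 5 with robust estimation, 7 with DESeq2 and the block and 3 with limma-voom and the number as a random block.

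Of the immediate early genes, which are transcribed within minutes of a stimulus, a minority passed the test, although 36 of 41 had a log2 change above 0 and 25 were higher in all 3 pairs. Of 41 measured members 13 rose, 0 fell and 28 did not pass, and adjusted over the list alone 23 were higher and 1, Ier5, was lower (-0.26). Besides 7 members shared with the CREB list, the genes that rose were Fosl2, Klf4 (0.55 ± 0.10), Junb (0.49 ± 0.09), Maff (0.43 ± 0.09), Btg2 (0.41 ± 0.07) and Btg1 (0.40 ± 0.07). Egr1 had a log2 change of 0.07 ± 0.06, Fosb 0.53 ± 0.15, Npas4 0.27 ± 0.31, Arc -0.22 ± 0.12 and Myc 0.00 ± 0.04, none of which passed. The paired camera test gave adjusted p = 2.07e-57 with the preset correlation and adjusted p = 0.268 with an estimated correlation, and fry within pairs gave adjusted p = 0.302. With limma-voom and the block 12 members were called, with robust estimation 3, with DESeq2 and the block 5 and with the random block 1, and leaving out pair 2, 3 or 4 gave 25, 9 or 15.

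Among the lists with 1 or 2 members that rose, 5 ranked higher in the paired camera test with the preset correlation, and some of them share such a member. Of 9 measured NFAT and calcineurin targets 2 rose (Nr4a1 and Ptgs2, 3 adjusted over the list alone), of 14 NF-κB and cytokine genes 1 rose (Ptgs2, 3 over the list alone), and of 14 glucocorticoid response genes 1 rose (Per1, 2 over the list alone). Of 18 circadian clock genes 2 rose, Per1 and the orphan receptor gene Rora (0.53 ± 0.06), with 3 over the list alone. Of 25 growth factors and receptors 2 rose, Fgfr2 and Vgf, with 6 higher and 1 lower over the list alone. In the last group Pdgfb had a log2 change of -1.58 ± 0.45 and did not pass (adjusted p = 0.268). The 5 lists had adjusted p = 1.46e-10, 3.27e-06, 2.59e-05, 0.000160 and 7.46e-08 in that order. With an estimated correlation the adjusted p was 0.247 for the growth factors and 0.268 for the other 4.

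ERK feedback genes, which are induced when the MAP kinase ERK is active, did not move together within pairs. None of 20 passed over all genes (edgeR with the block). Adjusted over the list alone 3 were higher, Ier3 (0.35), Spry1 (0.19) and Spry2 (0.19), and 3 were lower, Dusp6 (-0.31), Spry4 (-0.19) and Etv5 (-0.16), and the list test gave adjusted p = 0.937. The receptors of the agonist were expressed at low levels. Adra1a was at 1.82 ± 0.682 CPM in control and 2.99 ± 0.457 CPM in PE (log2 change 0.51 ± 0.22, adjusted p = 0.825), Adra1b changed by 0.04 ± 0.18 and Adra1d by 0.03 ± 0.20. Of the 6 measured adrenergic receptors 0 passed over all genes (list adjusted p = 0.208). None of 36 Gq and calcium signalling genes passed in either adjustment (list adjusted p = 0.543), and of 20 GPCR desensitisation genes the arrestin-domain gene Arrdc3 rose (0.29 ± 0.06; list adjusted p = 0.592). Of 21 SRF, YAP and actin genes 0 passed over all genes, with Ccn1 higher (0.47) and Vcl lower (-0.19) over the list alone and a list adjusted p of 0.798.

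The G2 and mitosis genes were slightly lower after PE within pairs. Their 32 measured members had a mean log2 change of -0.09 (-0.09, -0.08 and -0.09 in pairs 2, 3 and 4), and 21 of them were lower in every pair. None passed over all genes, and 8 were lower when adjusted over the list alone, led by Kif20b (-0.23 ± 0.05) and Aurka (-0.24 ± 0.05). The list ranked lower at adjusted p = 5.92e-11 with the preset correlation and adjusted p = 0.243 with an estimated correlation, and its members moved down on balance by fry (adjusted p = 0.0102). The 32 G1 to S genes had a mean change of -0.04, with 0 members past either adjustment (adjusted p = 0.00716, and adjusted p = 0.502 with an estimated correlation). Mki67 changed by -0.06 ± 0.04 and Ccnd1 by -0.08 ± 0.04, and neither passed. Of 16 cell cycle inhibitors, the antiproliferative genes Btg1 and Btg2 rose and 14 did not pass (list adjusted p = 0.675). Without the pairs both proliferation lists were called in the opposite direction, with mean changes of 0.23 for G1 to S genes (adjusted p = 2.78e-05) and 0.09 for G2 and mitosis genes (adjusted p = 0.00594), calls that were lost with adjusted p = 0.653 and adjusted p = 0.847 with an estimated correlation. Neither list was called higher when control replicate 1, control replicate 2, PE replicate 3 or PE replicate 4 was left out, with G1 to S means of -0.03, 0.06, 0.09 and -0.02 and G2 and mitosis means of -0.08, 0.06, 0.07 and -0.04 in that order. The first of these G2 and mitosis means was called lower (adjusted p = 0.000283).

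OPC identity genes showed no common shift. Of 20 measured OPC markers Tmem100 rose (0.83 ± 0.12), Olig2 fell and 18 did not pass (list adjusted p = 0.826), with Sox10 (-0.13 ± 0.04) also lower over the list alone. The platelet-derived growth factor receptor Pdgfra changed by 0.07 ± 0.03 and the NG2 proteoglycan gene Cspg4 by 0.05 ± 0.04, without passing. No member of the committed precursor list (19 genes) or the mature oligodendrocyte list (18 genes) passed either adjustment within pairs, and both lists had adjusted p = 0.675. Gpr17, counted here among the OPC markers, changed by -0.03 ± 0.03 and Mbp by 0.05 ± 0.04. Of 19 differentiation inhibitors 0 passed over all genes (list adjusted p = 0.725).

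Markers of other cell types were measured beside these. Microglia and macrophage markers (17 genes) had a median log2 change of 0.12 within pairs with 0 members past either adjustment and a list adjusted p of 0.0544, while Aif1 stayed below 1 CPM on average in both groups. Of 18 astrocyte markers only S1pr1 rose (0.38 ± 0.06; list adjusted p = 0.725), and Gfap changed by 0.00 ± 0.04. Of 17 neuron markers only the GABA-synthesis gene Gad1 rose (0.83 ± 0.13; list adjusted p = 0.208). Endothelial (11 genes), mural and leptomeningeal (15) and ependymal (5) markers had 0 members past the test over all genes, and list adjusted p of 0.108, 0.295 and 0.236. Adjusted over the list alone Kdr was higher (0.47 ± 0.13) and Col1a1 lower (-0.34). A single red blood cell gene was measured, so that list was not tested. Mitochondrially encoded genes (7) and ribosomal protein genes (46), read as signs of RNA quality, had 0 members past either adjustment and list adjusted p of 0.826 and 0.295. Of the metabolic and stress lists, the cholesterol synthesis (24 genes), glycolysis and hypoxia (25) and integrated stress (23) lists had 0 members past the test over all genes, with Xbp1 (0.25 ± 0.06) past it over its list alone, and of 14 heat shock genes the co-chaperone Bag3 rose (0.42 ± 0.06). Their list adjusted p were 0.295, 0.295, 0.236 and 0.295. Xist was at 823 CPM in control and 826 CPM in PE on average. Within pairs its log2 change was 0.10 ± 0.06, without passing, with ratios of 0.36, 0.03 and -0.07 in pairs 2, 3 and 4.

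**Figure D3:**
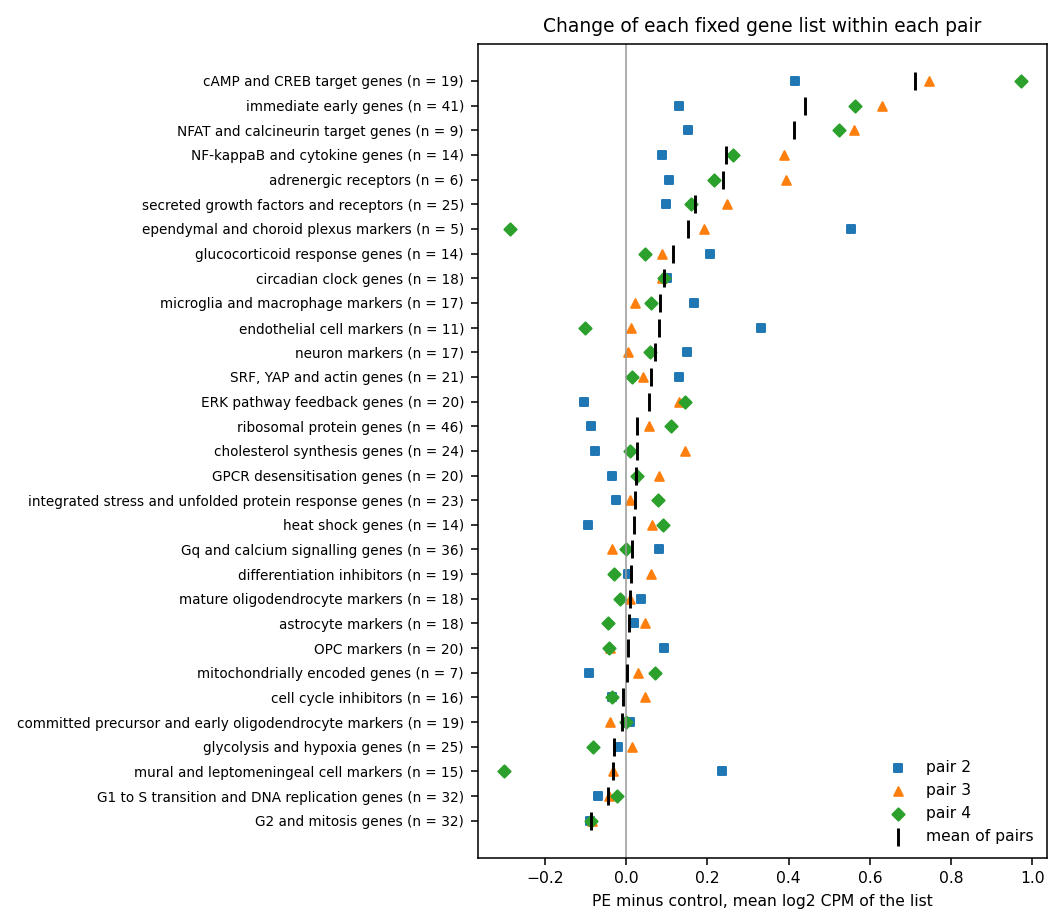
Difference between the PE and the control library of each pair (blue squares pair 2, orange triangles pair 3, green diamonds pair 4) in the mean log2 CPM of each of the 31 tested gene lists, with a black bar at the mean of the pairs and the number of measured genes in brackets. The cAMP and CREB target genes lie at 0.42, 0.74 and 0.97 and the G2 and mitosis genes at -0.09, -0.08 and -0.09.

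Without the pairs, the 4 control and 3 PE libraries gave 0 genes past the threshold by edgeR (smallest adjusted p 1.00), 71 genes at an unadjusted p under 0.05 where 796.7 would arise from uniform p-values, with 0 genes by limma-voom and 2, Cd14 and Fgfr2, by DESeq2. The 12 genes with the smallest unadjusted p among those higher in PE were Cd14, Fgfr2, Stc1, Ccrl2, Gem, Usp2, Cytip, Npr3, Crem, Neurl3, Bdnf and Csf2rb2, of which all but Neurl3, Bdnf and Csf2rb2 passed within pairs. Among those lower they were Gpr149, Elmod1, Peli3, Panx2, Pdgfb, Slc17a9, Trim21, Tnfrsf4, Il17rd, Pcdha7, Nlk-ps1 and Plekha4, with log2 changes from -1.34 ± 0.49 (Pdgfb) to -0.50 ± 0.20 (Il17rd), and none of these passed in either fit. Pcdha7 shares exons with its neighbours in the protocadherin cluster and Nlk-ps1 is a pseudogene, so reads of both could be split with related genes. With the preset correlation 14 lists ranked higher and 2 lower without the pairs (7 and 2 within pairs), and none was called with an estimated correlation (smallest adjusted p = 0.440) or by fry. Of these, the CREB, immediate early, NFAT, NF-κB, growth factor and circadian lists were called in the same direction within pairs. The ERK feedback, adrenergic receptor, Gq, GPCR desensitisation, microglia and neuron lists (higher) and the committed precursor and cholesterol lists (lower) were not called within pairs. Adjusted over the list alone, Fgfr2 was the sole member of any list past the threshold without the pairs.

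The paired calls rest on 3 pairs. Leaving out pair 2, 3 or 4 gave 253, 52 or 254 genes, limma-voom with the block gave 87 (79 higher and 8 lower, 84 of them among the 86), DESeq2 with the block gave 33 (31 higher and 2 lower), and exchanging treated and control libraries within some of the pairs called up to 11 lists against the 9 of the true assignment.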

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

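The tests of differences between replicate numbers, normalization, microglia and control replicate 1 were chosen only after the results they bear on were seen, and the counts over other splits of the libraries were planned. Of 99 genes and 32 lists examined in the control group, 5 genes and 2 lists had a library far from the other 3, and chance alone gives about 1 in 20. In control replicate 2, Arc was at 61.2 CPM (5.05 to 13.8 in the others), Klf4 at 62.7 CPM (30.4 to 35.3), Vgf at 338 CPM (78.5 to 106), Scg2 at 56.2 CPM (18.9 to 24.97) and the differentiation inhibitors at a mean log2 CPM of 5.82 (5.67 to 5.69). Control replicate 1 had Sox8 at 430.1 CPM (224 to 229 in the others). Control replicate 4 had ribosomal protein genes at a mean log2 CPM of 6.30 (6.11 to 6.12).

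The first pattern is the rise of CREB target and immediate early genes within pairs. The members of both lists that were called all lay in the direction that also separates pair 2 from pairs 3 and 4 (19 of 19, though 49 of the 52 measured members lie that way whether called or not). Of all 86 calls 76.7% did (exact 95% interval 66.4 to 85.2), against 58.3% of all tested genes. That interval counts genes as independent replicates, which they are not, so it may be too narrow. Treated libraries lying further along that difference may be considered as an explanation. Across the 52 measured members the PE change did not rank with that difference between pairs (Spearman rho 0.11 across genes, which are not independent replicates, bootstrap 95% interval -0.17 to 0.39). However, the difference was taken from pair means that include the PE libraries, so a larger PE change in pairs 3 and 4 lowers it. The rho therefore cannot decide on this explanation, which stays open. Scaling moves all genes of a library alike, yet the median log2 change of these members lay 0.284 above that of all other tested genes. The bootstrap 95% interval was 0.221 to 0.442 over genes, which are not independent replicates. These lists had already ranked above other genes in the paired camera test, so the gap restates that result and is not separate support. A single scaling factor per library cannot by itself produce such a gap. A response to handling of the treated dishes stays open beside the treatment, since no vehicle is named for the controls, and it was not tested.

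The second pattern is the rise of Cd14, Ccrl2 and Cytip, genes that microglia and macrophages express. More microglia in the treated libraries would need their markers to rise about as much, a log2 change of at least 1. The 17 measured markers had a median of 0.12 and at most 0.48. The 95% bootstrap interval of the median was 0.05 to 0.20 over genes, which are not independent replicates. The list mean differed by 0.17, 0.02 and 0.06 in pairs 2, 3 and 4. C1qb was at 6.64 CPM in control and 8.67 CPM in PE and Tyrobp at 5.22 and 7.17 CPM. These values argue against that amount. A smaller increase in microglia stays open, as does a change of these genes within a fixed number of microglia or in OPCs.

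The third pattern is the opposite direction of the G2 and mitosis genes with and without the pairs. Control replicate 1, which has no treated partner, had their lowest mean level, 6.47 log2 CPM against 7.08 to 7.59 in the other controls. Without it the mean change in the unpaired fit was -0.0818, since that fit holds the 3 pairs alone and so gives nearly the paired mean by design. The other libraries are balanced in pairs, so the opposite sign arises by arithmetic from counting control replicate 1 among the controls. The mean was also below 0 (-0.0380) without PE replicate 4. That fit leaves control replicate 4, the highest control at 7.59 log2 CPM, without a partner, so it does not bear on control replicate 1. Why control replicate 1 had a low level was not tested and stays open.

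The planned counts over other splits cover the numbers of called genes and lists and do not test any single pattern above. For genes within pairs, the real assignment gave 86 and the highest of the other assignments 0, and with 4 distinct assignments a share under 0.05 cannot be reached. For lists within pairs, 2 of 4 assignments gave as many, with 9 in the real one and 11 in the highest other. Without the pairs, 4 of 35 splits gave as many lists (16 real, 17 highest other), so chance cannot be excluded for that count. The real split gave 0 genes, so all 35 splits had to give at least as many, and that count decides nothing. A split of control 1, control 2 and PE 2 against the rest gave 7464 genes, which points to a structure of the samples. Of the 8 splits that part all 3 pairs, the others gave at most 13 lists and 0 genes.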

How the results depend on the processing

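The alternatives within pairs, except DESeq2 with the block, and the random block were chosen after the data were seen, and the others were planned. Without pairs the edgeR count of 0 genes stayed 0 under every other normalization, filter, threshold and left-out replicate and under limma-voom with or without sample weights. It became 86 (80 higher, 6 lower) with the replicate number as a block, 33 (31 and 2) with DESeq2 and the block, 2 (2 and 0) with DESeq2 alone and 8 (8 and 0) with limma-voom and a random block. The 16 lists became 9 with the block, 6 with no filter, 0 with an estimated correlation, 0 with fry and 6 to 13 with a replicate left out, the fewest without control replicate 1.

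Within pairs the 86 genes (80 higher, 6 lower) became 194 (171 and 23) with no filter, 88 (78 and 10) with robust estimation, of which 67 were shared, 112 (101 and 11) at a threshold of 0.1, 32 (31 and 1) at 1.5-fold or more and 33 (31 and 2) with DESeq2. With limma-voom it became 87 (79 and 8), of which 84 were shared. Leaving out pair 2, 3 or 4 gave 253 (193 and 60), 52 (48 and 4) or 254 (245 and 9) genes, and leaving out control replicate 1 gave 92. Other scalings gave 97 and 87 genes, each with the 86 among them. The 9 lists became 0 with an estimated correlation and 1 with fry.

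Among the named genes and lists, directions reversed in these cases, where at least 1 of the compared results was called. The camera direction of lists also changed with no call on either side, in 38 values without pairs and 18 within pairs. Maff, at -0.03 without pairs, was at 0.43 with the block. Of the called genes that are not named elsewhere, Utp14b (-0.14 without pairs, 0.42 with the block), Lrrtm2 (-0.10, 0.31), Camsap2 (-0.17, 0.22) and Prox1 (-0.01, 0.26) also had the other sign, and they are given here after their values were seen. With the block G1 to S genes had a mean log2 change of -0.0424, G2 and mitosis genes -0.0864 and cholesterol genes 0.0253. With a library left out of the unpaired fit, means ran from -0.0344 (without control replicate 1, and also negative without PE replicate 4) to 0.543 for G1 to S genes. They ran from -0.0818 (without control replicate 1, and -0.0380 without PE replicate 4) to 0.251 for G2 and mitosis genes, and from -0.154 to 0.0272 (without control replicate 1) for cholesterol genes. Without PE replicate 4 the cholesterol mean was -0.00018, which kept the sign of the main unpaired mean (-0.0788), and only the camera direction changed. The means ran from -0.374 (without PE replicate 2) to 0.650 for immediate early genes, from -0.254 (without PE replicate 2) to 0.494 for NFAT targets and from -0.0750 (without PE replicate 4) to 0.120 for ribosomal protein genes. Fewer samples and unequal replicate numbers in the groups follow from leaving out a library, and beyond that the cause was not tested. Of the values for single named genes, 1693 without pairs kept their side of the threshold (113 of them uncalled with the other sign) and 69 newly passed, and within pairs 981 kept it (10 uncalled with the other sign), 41 newly passed and 55 no longer passed. Genes under about 1 CPM, such as Tac1, Cytip and Ccrl2, are limited by depth.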

Other observations

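Untreated libraries differed between replicate numbers in lineage and proliferation genes. In controls 1 to 4, Gpr17, a member of the OPC marker list, was at 4587, 3268, 919 and 692 CPM. The G1 cyclin gene Ccnd1 was at 272, 476, 1785 and 2253 CPM and the proliferation marker Mki67 at 463.5, 701, 1102 and 1275 CPM. The committed precursor list had means of 7.47, 7.03, 6.602 and 6.004 log2 CPM in the same order and the G1 to S list 4.85, 5.69, 6.94 and 7.07. Each PE library was close to the control of its number, with Gpr17 at 3250, 909 and 668 CPM and Ccnd1 at 429, 1709 and 2188 CPM for numbers 2, 3 and 4.

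Rapid-response genes differed between the untreated libraries as well. Fos was at 377 and 492 CPM in controls 1 and 2 and 83.5 and 83.3 CPM in controls 3 and 4, Egr1 at 488, 456, 134.5 and 182 CPM and Nr4a1 at 294, 609.5, 95.5 and 88.4 CPM. The α1D receptor gene Adra1d was at 7.54 CPM in control 2 and 7.21 CPM in PE 2, against 0.970 to 2.60 CPM in the other libraries. Gfap was at 544 and 537 CPM in pair 2 and at most 258 CPM elsewhere. Xist was at 652 to 974.7 CPM in all libraries.

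A hypothesis formed after seeing these values is that the response of CREB targets is smaller where their control level is high. The control means of the list were 5.85, 4.87 and 4.63 log2 CPM in pairs 2, 3 and 4 and the changes 0.42, 0.74 and 0.97, the reverse order. A given order of 3 pairs arises by chance with 16.7% probability, so 3 pairs cannot decide this, and a lower level in the control also raises a log ratio by construction.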
